A study of Homo sapiens with 4 samples.

How the data were processed

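Transcript levels were measured in RKO, a human colon cancer cell line, transfected with the empty retroviral plasmid pLXSN (vector) or with pLXSN carrying SPARCL1. Each of the 2 transfected lines was grown for 72 h on plastic or on a Matrigel-coated dish, in RPMI 1640 with 10% serum. RNA was extracted with Trizol after trypsinization, and 6 ug of total RNA per sample was hybridized to 1 Affymetrix U133 Plus 2.0 array. This gave 4 groups with 1 array in each, so no group had a replicate, and the number of arrays limits the precision of every value. Groups were taken from the labels.

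A table of values for all 4 arrays and a comparison table for each surface were deposited by the authors. The value table held 1 linear intensity per probe set and array, deposited after a scaling step that is not stated: the trimmed mean over the central probe sets (2% trimmed) was 324.9, 324.3, 323.5 and 323.9 on the vector plastic, SPARCL1 plastic, vector Matrigel and SPARCL1 Matrigel arrays. MAS5 was named per the submitters' processing notes, without a version or settings. The comparison tables held, per the file headers, MAS5-style intensity values, other columns with detection calls (present, marginal or absent) and change calls, and a log2 signal ratio made by the authors. Their signals had a trimmed mean of about 500.1 on every array. They were not a constant multiple of the value table, so the summary step behind the value table is not known. Each column of the value table ranked closest to the same array's column of the comparison tables (Spearman's rho from 0.903 to 0.909, against at most 0.888 with another array). In the comparison tables the SPARCL1 array was the baseline, so the authors' log2 ratio was vector over SPARCL1, the opposite sign to the ratios given here. Lists of increased and decreased probe sets were deposited by the authors for each surface, as other files without a stated rule.

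Symbols came from the deposited annotation, and 39614 of the 40707 probe sets with a single gene were updated through their Entrez identifier. That step also resolved 60 symbols that a spreadsheet had turned into dates. The 1044 probe sets with several genes and the 12914 without a gene were left out of the gene counts. Each of the 19891 genes was represented by its probe set with the highest mean log2 signal over the 4 arrays. Coordinates are those of the deposited annotation (NCBI build 36.1), and are given only for probe sets with a single alignment.

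Ratios were log2 ratios of the value table's signals. A gene was measured in a contrast if its probe set was called present on at least 1 of the 2 arrays, and 12130 genes were measured in any contrast. Folds against an array without a present call are marked "at least". They were computed against the signal on that array, or against the lowest signal called present there if that was higher. Undetected signals are background, so these folds are nominal values and not strict lower limits. With the authors' own ratios some of them were smaller. Genes at least 2-fold higher or lower were counted in each contrast without a test, since 1 array per group leaves no replicate. The 2 contrasts between lines share no array, and neither do the 2 contrasts between surfaces, so each pair repeats a comparison on other arrays. A contrast between lines and a contrast between surfaces do share an array. Counts of genes past 2-fold in both contrasts of a pair stand beside the product of the single counts over the number of genes measured in both, and Pearson's r across genes is given without a p, since genes are not independent replicates.

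The only test was limma 3.58.1 (R 4.3.3) with an additive model of line and surface on log2 signals, lmFit and eBayes with trend. It left 1 residual degree of freedom per gene, and Benjamini-Hochberg adjusted p-values under 0.05 were called. The words rose and fell are used for calls of this model alone, and higher and lower for untested ratios. The error of this model is the difference between a gene's 2 ratios. It was moderated by eBayes with a prior shared across genes (24.9 degrees of freedom for the line, 43.2 for the surface). A gene's own disagreement between its ratios thus weighs little, and these p-values measure only the spread between these 4 arrays. They do not cover the spread between separate transfections, and 1 line per plasmid leaves the SPARCL1 plasmid and any earlier difference between the lines confounded.

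Gene lists were fixed before the data were examined, 27 in all, with 531 entries of which 526 had a probe set. For each list and contrast the median ratio of the measured members was placed among 10000 random lists of the same size, matched in 20 bins of mean signal (seed 11). The resulting percentile describes these arrays and is no p-value, since genes of a list vary together. Of the 90 placements in single contrasts, 36 lay outside 2.5 to 97.5, where the nominal share for random lists is 5%. In the simulation given below, 6 of 50 unshifted lists lay outside. Percentiles were given for lists with at least 5 measured members.

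The genes named follow a rule that was also fixed before the data were examined. It took the 12 genes highest and the 12 lowest in the SPARCL1-labelled line on both surfaces, by the smaller of the 2 ratios, up to 8 each way for Matrigel against plastic in both lines, and the 4 highest and 4 lowest for each contrast and for the difference of ratios, with a signal of at least 366.3, the median of present probe sets. From each list it took up to 4 measured members with the largest mean ratio. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.

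The procedure was tested on simulated data with 200 changed genes among 11060. The simulated noise was independent between arrays, with a spread taken from the observed differences of ratios, and each shift was the same on both surfaces. The additive model called 24 of 67 genes shifted 1.5-fold, 55 of 67 shifted 2-fold and 66 of 66 shifted 4-fold, and 1 of the 10860 unchanged genes. The simulated ratios correlated at r = 0.352, against 0.855 in the data, and no variation between cultures was simulated. These counts are therefore not the error rates of the real comparison. Of 50 lists of 20 genes without a shift, 6 lay outside the 2.5 to 97.5 range, more than the nominal share, and all 50 lists shifted by 0.3 on the log2 scale lay above it.

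Alternatives set before the data were examined were quantile normalization, no detection filter, a pseudocount of 14.2 (the median signal of absent probe sets), the median over a gene's measured probe sets, the additive model without its other factor, and for the authors' lists the value table's ratio. Chosen after the data were seen were the use of the comparison tables' signals, the minimum of 5 members for a percentile, the rule for switched-off genes and 3 further gene families in the closing section.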

Results

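Transcript levels of RKO colon cancer cells transfected with empty pLXSN or with pLXSN carrying SPARCL1 were compared on plastic and on Matrigel, a basement membrane extract. SPARCL1 encodes a secreted matricellular glycoprotein related to SPARC. Each of the 4 combinations was measured on 1 array, without replicates. Of 54675 probe sets, 23488 were called present on the vector plastic array, 23155 on the SPARCL1 plastic array, 23005 on the vector Matrigel array and 23598 on the SPARCL1 Matrigel array. The median signal intensity was 40.8, 40.5, 39.9 and 40.8 in the same order. The ratio of the 3′ to the 5′ control probe set of GAPDH lay between 0.911 and 0.924 and that of ACTB between 1.19 and 1.33, so RNA integrity by this measure was alike on the 4 arrays. Across 27279 probe sets, arrays of the same line correlated at r = 0.989 (vector) and 0.987 (SPARCL1), and arrays of different lines at 0.963 to 0.966.

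The transfected gene was examined first, as a check of the labels. SPARCL1 had 1 probe set on the array, which was called absent on all 4 arrays. Its signal intensity was 10.7 on the vector plastic array, 10.9 on the vector Matrigel array, 15.3 on the SPARCL1 plastic array and 19.4 on the SPARCL1 Matrigel array. The 4 signals were within the range of undetected transcripts, so no fold is given. The files do not say whether this probe set covers the transfected copy, and the SPARCL1 labels were therefore neither supported nor contradicted by this gene. The arrays are named by their labels throughout, and SPARCL1-labelled line means the cells the labels describe as transfected with pLXSN-SPARCL1. The related gene SPARC, with 2 probe sets, was also called absent on all 4 arrays.

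The comparison of the SPARCL1-labelled line with the vector line asks which transcripts differ with SPARCL1 transfection. The differences were large and were mostly the same on plastic and on Matrigel. The most lowered transcripts in the SPARCL1-labelled line were those of AREG (amphiregulin, an EGF receptor ligand), THBS1 (thrombospondin 1, a matricellular protein), CLEC2B (a C-type lectin) and BTG3 (an antiproliferative protein). The most raised was RGS4, a regulator of G protein signalling. On plastic 272 of 11583 measured genes were at least 2-fold higher and 327 at least 2-fold lower, and on Matrigel 299 and 327 of 11607. At least 4-fold, 43 were higher and 143 lower on plastic, and 51 were higher and 134 lower on Matrigel.

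Across the 11060 genes measured on both surfaces, the 2 ratios correlated at r = 0.855 (Spearman's rho 0.640). At least 2-fold higher on both surfaces were 149 genes, where independent ratios would share 5.67, and 225 were lower on both, where 7.73 would be shared. Only 2 genes passed 2-fold in opposite directions. At least 16-fold on both surfaces were 41 lower and 0 higher genes. The additive limma model called 2623 genes, of which 1443 rose and 1180 fell with the SPARCL1 label, and 484 of them by at least 2-fold. The calls included 373 of the 374 genes past 2-fold on both surfaces. In 65 of the calls the 2 ratios differed by at least 2-fold from each other.

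**Figure D1:**
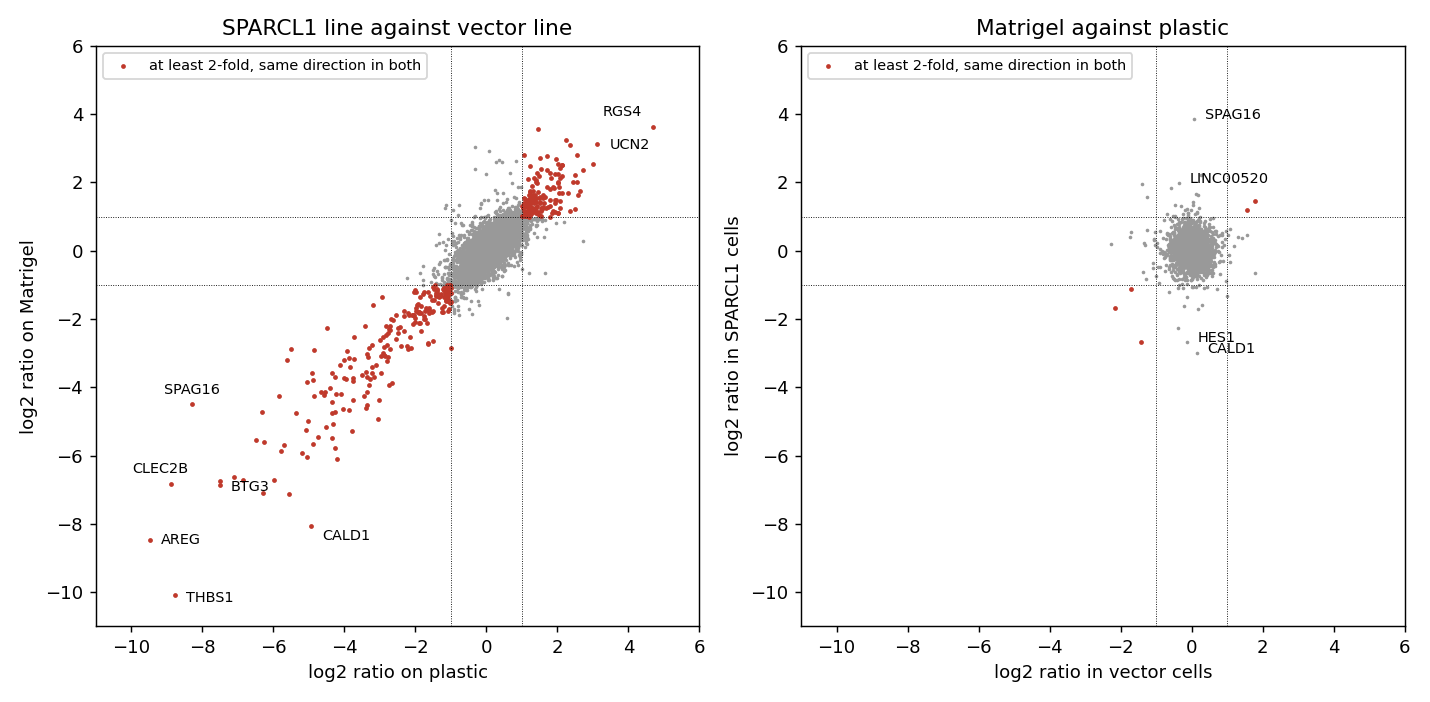
Log2 signal ratio of each measured gene in the 2 contrasts between lines (left, plastic on the x axis and Matrigel on the y axis) and in the 2 contrasts between surfaces (right, vector cells on the x axis and SPARCL1-labelled cells on the y axis), with genes at least 2-fold the same way in both in red and dotted lines at 2-fold. The ratios between lines follow the diagonal (r = 0.855, 374 red genes), and those between surfaces do not (r = -0.06, 5 red genes).

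The AREG signal was 8820 on the vector plastic array and 12.5, without a present call, on the SPARCL1 plastic array, at least 708-fold lower. On Matrigel it was 9708 against 27.3, or 356-fold lower (adjusted p = 8.79e-24 by limma). AREG is on chromosome 4, and AREGB, a near-identical copy whose probe set may read the same transcript, was also among the 12 lowest genes. THBS1 (chromosome 15, 37660639 to 37676957) was at least 315-fold lower on plastic and at least 293-fold lower on Matrigel by its brightest probe set. All 4 of its probe sets with a present call were lower, the others by log2 ratios of -2.58 to -4.47 on plastic and -2.50 to -6.41 on Matrigel. CLEC2B (chromosome 12, 9897071 to 9913219) was at least 470-fold and at least 115-fold lower, marginal instead of absent on the SPARCL1 Matrigel array. BTG3 (chromosome 21, 17887841 to 17888517) was at least 180-fold and at least 117-fold lower, in 2 of its 3 detected probe sets. The remaining detected probe set, dim and on the other strand, was higher by 1.07 on plastic. The other genes among the 12 lowest were CADM1 (a cell adhesion molecule), CYB5A (cytochrome b5), TNS4 (a tensin of focal adhesions), TIMP2 (a metalloprotease inhibitor), PNMA2, MNS1 and CA2 (carbonic anhydrase 2). Their lowest fold was at least 48.2, for CA2 on Matrigel, and their highest was at least 139, for CYB5A on plastic. The authors' log2 ratios of vector over SPARCL1 differed in size both ways. They were smaller for TNS4 (3.2 on plastic and 5.1 on Matrigel, against -6.29 and -7.10 here) and larger for TIMP2 on Matrigel (8.7 against -6.70).

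RGS4 (chromosome 1, 161305817 to 161311001) had a signal of 66.9 on the vector plastic array and 1727 on the SPARCL1 plastic array, 25.8-fold higher. On Matrigel it was 86.7 against 1069, or 12.3-fold higher (log2 SE 0.179 in the limma model, adjusted p = 3.39e-16). UCN2, the peptide hormone urocortin 2 (chromosome 3, 48574156 to 48576205), was called present on the SPARCL1 arrays alone, at least 8.65-fold higher on plastic and at least 8.81-fold on Matrigel, but with the signals of the authors' comparison tables its mean log2 ratio was 1.48 instead of 3.13. GFPT2, an enzyme of hexosamine synthesis (chromosome 5, 179660305 to 179712921), was 7.95-fold and 5.80-fold higher. BNC2, a zinc finger protein, was 5.87-fold and 6.98-fold higher. ARG2, the mitochondrial arginase, was 4.76-fold and 9.48-fold higher. TRPV2, a cation channel, was at least 5.08-fold and at least 8.60-fold higher. The crosslinking enzyme TGM2 was 4.38-fold and 4.57-fold higher, by 1 of its 3 detected probe sets. The chemokine receptor CCR10, the related CCRL2, EVC, CCDC141 and the dim transcript CCDC26 made up the rest of the 12. Their log2 ratios lay between 2.07 and 2.72, and were taken against undetected signals for CCDC26 and, on plastic, for EVC. By the median over a gene's measured probe sets, the mean log2 ratio was 1.58 for ARG2, 1.35 for EVC and 0.84 for TGM2, each smaller than by the brightest probe set. THBS1, CADM1 and TNS4 also had smaller ratios that way, but against undetected signals.

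**Figure D2:**
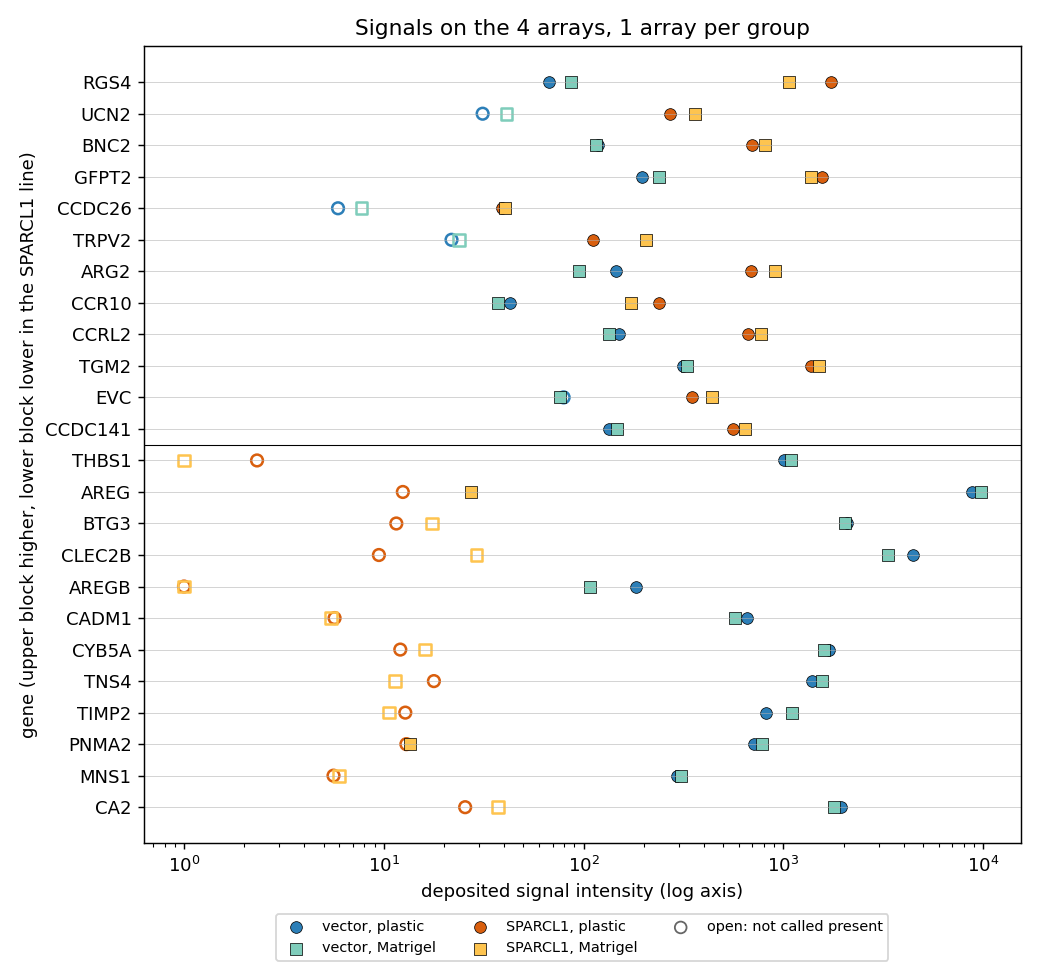
Deposited signal intensity (log axis) of the 12 genes highest and the 12 lowest in the SPARCL1-labelled line on both surfaces, with 1 point per array and open points where no present call was made. The 2 vector arrays lie close together and far from the 2 SPARCL1 arrays for every gene, as for AREG at 8820 and 9708 against 12.5 and 27.3.

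On single surfaces, the brightest differences added a few genes. On plastic, KRT81, a hair keratin, was at least 33.4-fold higher, but it had no present call on either Matrigel array, so its difference there rests on undetected signals. The authors' log2 ratio of vector over SPARCL1 on Matrigel was -2.2, with a decrease call, the same direction as on plastic. ANGPTL4, a secreted regulator of lipoprotein lipase, was 6.19-fold higher on plastic and 3.37-fold on Matrigel. SPAG16, a sperm axoneme protein, was at least 242-fold lower on plastic and 22.7-fold lower on Matrigel. On Matrigel, CRYM (mu-crystallin) was at least 11.7-fold higher and XK (a membrane transport protein) at least 131-fold lower. CALD1 (caldesmon, an actin-binding protein) was at least 267-fold lower on Matrigel and 30.5-fold lower on plastic.

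Epithelial junction genes with a present call were lower in the SPARCL1-labelled line. The list median was -0.76 on plastic and -0.89 on Matrigel (15 measured genes each, percentile 0 on both), and 9 of 14 genes in the limma model fell (9 also when adjusted over the list alone, where 1 rose). Over all 30 members, detected or not, the medians were -0.02 and -0.23. EPCAM was lower by log2 ratios of -3.73 and -3.18, the desmosomal protein DSP at least 13.5-fold on plastic and 20.6-fold on Matrigel, and the desmosomal protein PKP3 by -1.63 and -1.69. Mesenchymal genes did not move the other way as a group. Their medians were 0.01 and 0.00 with means of -1.17 and -1.15, because 3 members were much lower. TAGLN (transgelin) was lower by -5.05 and -6.04, S100A4 at least 29.4-fold and at least 50.9-fold, and the transcription factor SNAI2 at least 32.6-fold and at least 31.8-fold. The transcription factor ZEB1 was higher, by 1.60 and 1.64, and the receptor AXL was near 0 (0.01 and -0.14). In the limma model 2 of 9 mesenchymal genes rose and 3 fell (3 and 3 adjusted over the list alone).

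Genes of the cell surface and matrix went both ways. In the list of SPARC family and related matricellular genes, with 7 and 6 measured members, the median was -0.71 on plastic (percentile 1.63) and -0.16 on Matrigel (percentile 27.3), but with the signals of the authors' comparison tables the plastic median was 0.37. Over all 19 members, detected or not, the medians were -0.12 and 0.34. Besides THBS1, CCN3 was called absent in the SPARCL1-labelled line on both surfaces (at least 45.0-fold and at least 7.33-fold lower), and CCN1 was higher (0.36 and 0.34). For integrins and focal adhesion genes the medians were 0.09 and -0.04, and the means were -0.33 and -0.35. Here the caveolar protein CAV1 (-4.85 and -4.25) and the hyaluronan receptor CD44 (at least 29.1-fold and 7.45-fold) were lower, and the integrin subunits ITGA3 (at least 3.73-fold and at least 3.59-fold) and ITGA2 (2.83-fold and 1.94-fold) were higher. The limma model had 5 of 16 rising and 4 falling (5 and 5 adjusted over the list alone). For basement membrane and extracellular matrix genes the median was -0.06 on plastic (percentile 22.5) and -0.33 on Matrigel (percentile 0.310). The laminin chain LAMB1 was at least 21.0-fold and at least 16.2-fold lower, while LAMC1 (0.77 and 0.78) and LAMB3 (0.81 and 0.33) were higher. Matrix proteases and inhibitors had medians of -0.03 and 0.03, with TIMP2 and SERPINE2 (at least 17.1-fold and at least 18.5-fold) lower and TIMP1 (0.64 and 0.53) higher.

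Mitosis genes were lower in the SPARCL1-labelled line, with medians of -0.35 and -0.54. All 25 members were below 0 on plastic and 24 on Matrigel (percentile 0 on both), and 21 of 25 fell in the limma model (24 adjusted over the list alone). The kinetochore motor CENPE (-1.32 and -1.30), the kinesin KIF20A (-1.10 and -1.30), CENPF (-0.64 and -1.16) and the kinase PLK1 (-0.64 and -1.09) were the lowest. S phase and DNA replication genes differed less, with medians of -0.06 and -0.10 (both inside the range of random lists), and 4 of 24 fell (3 adjusted over the list alone), TYMS among them (-0.21 and -0.33).

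Interferon-stimulated genes were lower, with medians of -0.57 (18 genes) and -0.41 (19 genes), percentile 0 on both. Over all 25 members, detected or not, the medians were -0.54 and -0.22. MX1 was lower by -2.77 and -2.42, IFIT1, without a present call in the SPARCL1-labelled line, at least 9.08-fold and at least 3.01-fold, and PSMB9 by -1.77 and -0.44. In the limma model 11 of 18 fell, over the list alone as well. NF-kB and cytokine genes had medians of -0.25 and -0.36 (percentiles 0.950 and 0.170), over 10 measured members. Over all members, detected or not, the medians were 0.00 and -0.03. CSF2 (GM-CSF, at least 17.5-fold and 10.1-fold) and BIRC3 (at least 7.53-fold and 5.77-fold) were lower and LIF was higher (1.15 and 1.12).

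Immediate early genes had medians of 0.56 on plastic and 0.27 on Matrigel (percentiles 100 and 99.4), but the mean on Matrigel was -0.28. In the limma model 8 of 15 rose and 5 fell (8 and 5 adjusted over the list alone). The phosphatase DUSP1 (2.29 and 1.69) and the transcription factor EGR3 (1.48 and 1.05) were higher. The transcription factors KLF4 (-4.28 and -5.77) and NR4A1 (at least 4.52-fold and at least 3.67-fold) were lower. MAPK output genes had medians of 0.16 (percentile 98.2) and 0.02, with means of -0.54 and -0.50, and SPRY2 was higher (0.60 and 0.81).

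Among the stress response lists, metallothioneins had medians of -0.15 and -0.44 (percentiles 2.33 and 0), and all 7 fell in the limma model (7 adjusted over the list alone), MT1M most (-1.43 and -1.32). With the comparison tables' signals their median on plastic was 0.02. Heat shock and chaperone genes had medians of -0.13 and -0.41 (percentiles 3.75 and 0.010), and 7 of 10 fell (8 adjusted over the list alone), DNAJB1 by -0.60 and -0.72. Genes of the unfolded protein and amino acid stress response had medians of -0.03 and -0.24 (percentiles 45.4 and 0.030). Hypoxia and glycolysis genes had medians of 0.08 and 0.19 (percentiles 92.0 and 99.7), with the hexokinase HK2 higher (2.64-fold and 1.70-fold) and the peptide ADM lower (-1.37 and -0.68). NRF2 targets had medians of -0.11 and 0.07, within the random range. Cholesterol synthesis genes had medians of 0.17 (percentile 98.4) and 0.09 (percentile 84.1). The p53 targets had a median of -0.31 on plastic (percentile 0) and 0.17 on Matrigel (percentile 96.2).

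The other lists had medians inside the random range or few measured members. Wnt and beta-catenin targets had medians of 0.18 and -0.02, and 3 of 8 rose in the limma model (3 adjusted over the list alone), SOX9 most (1.37 and 1.52). TGF-beta targets had medians of 0.16 and 0.08, and 4 of 10 rose and 2 fell (5 and 3 adjusted over the list alone), with LTBP2 higher (2.02 and 1.11) and BAMBI lower (-1.51 and -1.76). Intestinal stem and differentiation markers had medians of 0.23 (7 genes) and -0.49 (4 genes, CA2 among them), and the plastic median was -0.56 with the comparison tables' signals. Ribosomal proteins had medians of -0.05 and -0.03 (0.00 and 0.03 under quantile normalization), and 0 of 24 were called by limma. Fibroblast markers had 1 and 2 measured genes, endothelial markers 2 and 0, immune cell markers 2 and 2, and neuroendocrine and neural markers 3 and 4. None of the measured genes of these 4 lists was 2-fold different between the lines.

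**Figure D3:**
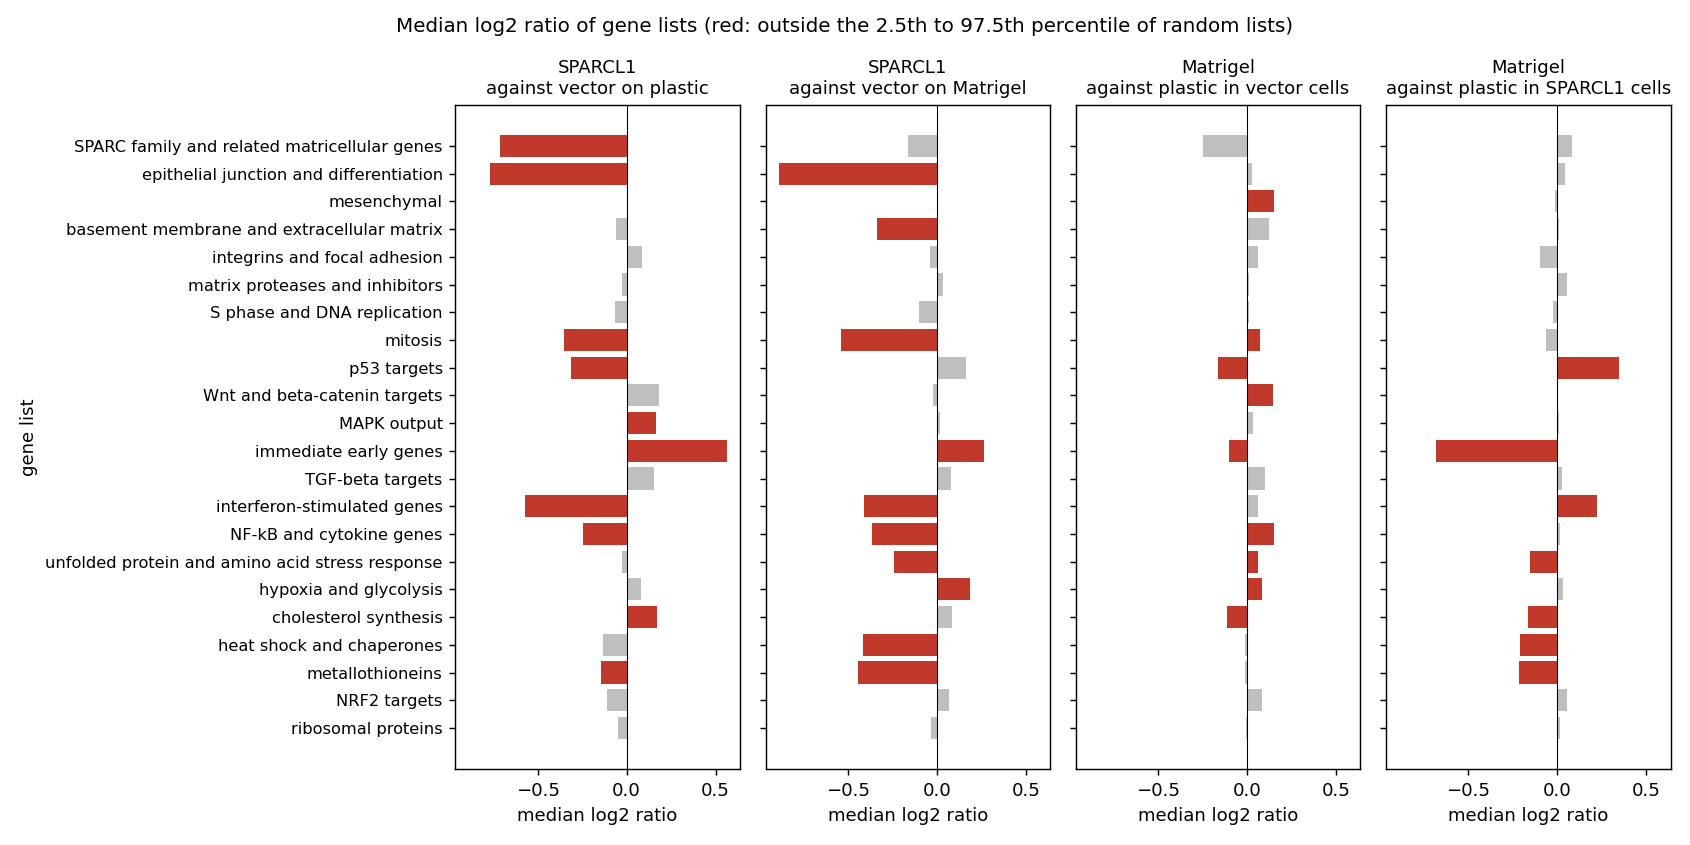
Median log2 ratio (x axis) of the measured members of 22 gene lists (y axis) in each of the 4 contrasts, in red where the median lay outside the central range of random lists. Epithelial, mitosis and interferon lists lie below 0 in both contrasts between lines, and the p53 target list lies below 0 in vector cells (-0.16) and above 0 in SPARCL1-labelled cells (0.34) for Matrigel against plastic.

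The comparison of Matrigel with plastic asks what the matrix coating does to each line. Differences were far smaller than those between lines and were mostly not shared by the lines. In vector cells 32 of 11471 measured genes were at least 2-fold higher and 57 lower on Matrigel. In SPARCL1-labelled cells 59 of 11515 were higher and 55 lower. The SD of the ratios was 0.244 and 0.285 on the log2 scale, against 0.633 and 0.641 between the lines. Across 10856 genes the 2 ratios correlated at r = -0.06 (Spearman's rho -0.12). Their disagreement gave an SD of 0.228 per ratio, close to the SD of 0.244 in vector cells. Matrigel differences seen in 1 line alone can therefore not be told apart from variation between single arrays. At least 2-fold higher in both lines were 2 genes (HNRNPA3P1 and CASS4), where independent ratios would share 0.028, and 3 were lower (PABPC1L2B, ACTG1P17 and UNQ6487), where 0.041 would be shared. All 5 were dim, with a highest signal of 86.7 (UNQ6487) and absent or marginal calls on some arrays.

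The additive limma model called 15 genes for Matrigel, 6 rising and 9 falling, and 361 genes had an unadjusted p under the same threshold. Among the genes lower on Matrigel in both lines, 2 immediate early transcription factors had the smallest adjusted p. FOS was lower by -0.64 in vector cells and -1.21 in SPARCL1-labelled cells (adjusted p = 0.000798), and EGR1 by -0.36 and -1.02 (adjusted p = 0.000798). VMP1, a protein of autophagosome formation, was lower by -0.93 and -0.95 (limma adjusted p = 0.00125). The probe set annotated as MIR21, a microRNA gene of the same locus, was lower by -0.63 and -0.49 (limma adjusted p = 0.0149). These 2 calls may not be separate readings. KRT7, a simple epithelial keratin, was higher by 1.02 and 0.45 (adjusted p = 0.00125), as was SMAD3, a mediator of TGF-beta signalling, by 0.61 and 0.95 (adjusted p = 0.00482). MIR21 and SMAD3 were named after their values were seen. In 5 of the 15 calls the 2 ratios differed by at least 2-fold, so the call rested mostly on SPARCL1-labelled cells: CD44 (0.26 and 2.23), SPAG16 (0.07 and 3.85), ZNF114 (0.12 and 1.67), HES1 (-0.13 and -2.67) and CALD1 (0.15 and -2.98). The last had ratios of opposite sign. CD44 and SPAG16 on plastic and CALD1 on Matrigel had no present call in SPARCL1-labelled cells, so their ratios there rest on an undetected signal. Without the term for the line, limma called 0 genes, with 19 at an unadjusted p under the threshold.

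In vector cells the highest bright genes on Matrigel were keratins, KRT80 by 1.19, KRT7 by 1.02 and KRT8 by 0.66, with TOX2 (0.77). The lowest were the histone genes H2AC8 (-0.99), H1-2 (-0.89) and H2AC6 (-0.80), with VMP1. In SPARCL1-labelled cells the highest were LINC00520 (1.97), ZNF114 (1.67), CRYM (1.24) and GDAP1 (1.19). The annotation places the LINC00520 probe set on chromosome 17, so its assignment to that gene is uncertain. The lowest were HES1, a Notch target (-2.67), KRT81 (-1.22, without a present call on Matrigel), FOS and the zinc transporter SLC30A1 (-1.10).

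Immediate early genes were lower on Matrigel in both lines. The median was -0.10 in vector cells (16 genes, percentile 0.90) and -0.68 in SPARCL1-labelled cells (14 genes, percentile 0), and 2 of 14 fell in the limma model (7 adjusted over the list alone). Cholesterol synthesis genes were slightly lower in both, with medians of -0.11 and -0.17 (percentiles 0.130 and 0.020). HMGCS1 was lower by -0.34 and -0.38, and 0 of 21 were called by limma (0 adjusted over the list alone). Interferon-stimulated genes had medians of 0.06 (percentile 88.4, and 0.00 with the comparison tables' signals) and 0.22 (percentile 100.0), and 0 of 17 were called. Metallothioneins had medians of -0.01 (0.21 with the comparison tables' signals) and -0.22 (percentiles 34.7 and 0), with 0 called and 5 falling adjusted over the list alone. Heat shock genes had medians of -0.01 and -0.21 (percentiles 36.4 and 0).

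The p53 targets went opposite ways. In vector cells 18 of 22 were below 0 on Matrigel (median -0.16, percentile 0), and in SPARCL1-labelled cells 18 of 22 were above 0 (median 0.34, percentile 100). The stress-induced TP53INP1 was -0.59 and 1.85, the cytokine GDF15 -0.48 and 1.02, and the p53 ubiquitin ligase MDM2 -0.30 and 0.59. None of the 22 was called by limma for a Matrigel effect common to both lines. The unfolded protein list also differed, with medians of 0.06 (percentile 97.55) and -0.15 (percentile 0). The difference between the lines was not tested for either list, since 1 array per group allows no test of it.

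The remaining lists had small medians. Those for mitosis (percentile 99.7), hypoxia (99.3), mesenchymal (98.0), NF-kB (98.0) and Wnt (97.8) genes lay above the random range in vector cells and inside it in SPARCL1-labelled cells. In vector cells and SPARCL1-labelled cells the medians were 0.07 and -0.06 for mitosis, 0.01 and -0.03 for S phase, 0.15 and -0.01 for mesenchymal genes, 0.03 and 0.04 for epithelial genes, and 0.06 and -0.10 for integrins. They were 0.15 and 0.00 for Wnt targets, 0.15 and 0.02 for NF-kB genes, 0.08 and 0.03 for hypoxia genes, and 0.09 and 0.05 for NRF2 targets. They were -0.25 and 0.08 for matricellular genes, 0.12 and 0.01 for basement membrane genes, 0.01 and 0.05 for proteases, 0.04 and 0.01 for MAPK output, 0.10 and 0.03 for TGF-beta targets, -0.13 and -0.29 for intestinal markers, and 0.00 and 0.02 for ribosomal proteins.

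The third comparison asks which differences between lines depended on the surface, or equally which Matrigel differences depended on the line. By this untested difference of ratios, 153 of 11060 genes differed by at least 2-fold, 93 with a higher ratio on Matrigel and 60 with a lower one. Among bright genes the highest were SPAG16 (3.78), LINC00520 (2.33, by the probe set of uncertain assignment), CRYM (2.10) and CLEC2B (2.04). The lowest were CALD1 (-3.13), HES1 (-2.54), XK (-1.57) and KLF4 (-1.49). SPAG16, CLEC2B, CALD1, XK and KLF4 were much lower in the SPARCL1-labelled line on both surfaces, so for these the difference rests on dim signals. XK and CLEC2B had no present call on either SPARCL1 array, SPAG16 and CALD1 had one on a single SPARCL1 array, and CRYM had none on either vector array, so their values and ranks rest partly or wholly on undetected signals. HES1 was higher in the SPARCL1-labelled line on plastic (0.57, signals 453 against 305) and lower on Matrigel (-1.97, signals 71.0 against 278). The probe set annotated as LINC00520 was 6.00-fold higher on Matrigel and 1.20-fold higher on plastic.

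The authors' deposited lists were described as they stand. They held 705 probe sets higher in vector and 525 higher in SPARCL1 cells on plastic, and 729 and 659 on Matrigel. Every entry had an absolute log2 signal ratio of at least 1, a change call in its direction and a present call on the brighter array. The full tables held 705, 525, 730 and 659 probe sets meeting this rule. Shared between the surfaces were 431 entries higher in vector and 262 higher in SPARCL1 cells. By the value table's ratio, 1944 of the 2618 entries were at least 2-fold in the listed direction, or 77.0%, 75.8%, 74.2% and 70.1% of the 4 lists.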

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

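The tests for loss of chromosome segments and for the step behind the value table were set before their results were seen, and the tests for exchanged arrays, for the probe set's position, for the chromosome 4 stretch, for detection and for a whole-array shift were chosen after the results were seen. The rule for switched-off genes was chosen after the data were seen as well. With 1 array per group, the differences between ratios given in this part were not tested.

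SPARCL1 was called absent on the 2 arrays of cells labelled as transfected with it. Arrays of the vector and SPARCL1 lines exchanged would put the transcript on the vector-labelled arrays, and 0 of the 2 had a present call, so an exchange does not account for the absence. This does not show that the labels are right, since the probe set may not read the transfected copy. A transfected copy present but outside the probe set stays open, since the gene had 1 probe set and the files give no probe positions. Too little expression of the plasmid was not tested.

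In the SPARCL1-labelled line, 62 genes were switched off, meaning called present on both vector arrays, absent on both SPARCL1 arrays and at least 4-fold lower on each surface, against 3 genes switched on (KCNQ1, TRPV2 and UCN2). Loss of chromosome segments would place them side by side, but of the 59 with a single alignment 3.39% had a switched-off measured neighbour (1 pair, MAL2 and CCN3, as many as in 28.8% of random draws). Over 117 measured neighbours the median log2 ratio was 0.006 on plastic and -0.026 on Matrigel. Loss of 1 gene alone, or of a run whose other genes were lowered less, would escape the count. Loss of the chromosome 4 stretch of AREG, AREGB, BTC and PARM1, a run of low genes of which that count took PARM1 alone as switched off, stays open, since 2 of the 4 were called absent on both SPARCL1 arrays and AREG and BTC kept dim present calls. By the signals of the separately processed comparison files, 100% of the 62 were at least 2-fold lower on both surfaces, which argues against the step that made the value table, although their choice through the same detection calls partly fixes this outcome, and lower detection on the SPARCL1 arrays was argued against by 593 more present calls on the SPARCL1 Matrigel array than on the vector Matrigel array, although the SPARCL1 plastic array had fewer than its vector partner. An effect of SPARCL1, a difference between the lines that preceded transfection and the outgrowth of a clone or of another epithelial cell population stay open as untested, and may each account for such a pattern.

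The p53 target list had a median ratio for Matrigel against plastic of -0.16 in vector cells and 0.34 in SPARCL1-labelled cells, a difference of 0.51 that stood out because the medians had opposite signs. A shift of the whole SPARCL1 Matrigel array would move genes of like signal alike. The list lay at percentile 100 among random lists matched in signal, which was already known, and after scaling the median over all measured genes was -0.0029. The percentile argues against a whole-array shift, but not against a difference of the list's genes on 1 array. The median near 0 adds nothing to this, since the arrays had been scaled to nearly equal trimmed means. Between the lines the list's median was -0.31 on plastic (percentile 0) and 0.17 on Matrigel (percentile 96.2). The low SPARCL1 plastic array thus contributes to the difference. A p53 response to Matrigel that differs between the lines is one hypothesis and was not tested. A difference in the density or handling of 1 dish stays open, since 1 array per group does not separate it.

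Other results differed between lines or surfaces in opposite directions. The stress-induced gene TP53INP1 was lower in the SPARCL1-labelled line on plastic (-1.18) and higher on Matrigel (1.25), a difference of 2.43. TXNDC8, a dim transcript with a highest signal of 23.6, was lower on plastic (-1.13) and higher on Matrigel (1.33, absent on the SPARCL1 Matrigel array), a difference of 2.46. LY96, an accessory protein of Toll-like receptor 4, was lower on Matrigel in vector cells (at least 2.39-fold, absent on the vector Matrigel array) and higher in SPARCL1-labelled cells (1.59). Its difference of 2.84 thus rests on an undetected signal, and its highest signal was 79.6. The cancer-testis gene MAGEB2 was lower on Matrigel in vector cells (-1.40) and higher in SPARCL1-labelled cells (1.95), a difference of 3.35. It was dim, with a signal of 15.5 on the vector Matrigel array and a highest signal of 127. On Matrigel the authors' log2 ratio of vector over SPARCL1 was -1.8, smaller in size than the 3.035 of SPARCL1 over vector here. For HES1 the ratio of SPARCL1-labelled to vector cells on Matrigel minus that on plastic was -2.54. The list of the unfolded protein and amino acid stress response had medians of 0.06 in vector cells and -0.15 in SPARCL1-labelled cells for Matrigel against plastic, a difference of -0.22.

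Probe sets without a single gene symbol stand outside the gene counts. Of these 13906 probe sets, 2905 were measured on both surfaces, 37 were at least 2-fold higher and 29 at least 2-fold lower in the SPARCL1-labelled line on both, and their ratios correlated at r = 0.548, less than those of the named genes. Named genes were each read by their brightest probe set alone, so these correlations cover unlike sets.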

How the results depend on the processing

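Alternatives were set before the data were examined, except the use of the comparison tables' signals, which was chosen after the data were seen. Under quantile normalization all 19 main results kept their direction and stayed within 1.5 times their count. Of 24 named genes and 42 list medians over a pair of contrasts, 66 in all, none moved by more than its spread under quantile normalization, 3 moved without the filter, 16 with the pseudocount, 8 with the median over probe sets (all of them genes) and 12 with the comparison tables' signals, with which 1 further median outside the random range reversed. The 3 without the filter were the epithelial (-0.877 to -0.033), NF-kB (-0.333 to -0.032) and protease lists (0.085 to -0.16) between the lines. Medians near 0 also changed sign in some settings. The cause of each other difference was not tested, except where a setting by its construction adds or removes dim genes.
Without the detection filter, dim genes entered, and genes higher and lower were 1344 and 1202 for the lines on plastic, 1444 and 1333 on Matrigel, 987 and 1016 for Matrigel in vector cells, and 973 and 1050 in SPARCL1-labelled cells. Shared between surfaces were 418 higher and 447 lower (r = 0.318, additive model 1155), shared between lines 201 and 197 (r = -0.005, additive model 0, with 616 at an unadjusted limma p under the threshold), and 3121 genes differed between ratios.
With the pseudocount, which shrinks the ratios of dim genes, Matrigel had 4 and 5 genes in vector cells and 22 and 14 in SPARCL1-labelled cells, 0 and 0 shared (r = -0.093), 65 genes differed between ratios, and the mean log2 ratio of the undetected SPARCL1 signals, no measure of expression, was 0.335 instead of 0.679.
With the median over probe sets, 52 genes were higher on Matrigel in vector cells, 4 were higher in both lines (r = -0.024), and r between the line ratios was 0.832.
With the comparison tables' signals, Matrigel had 109 and 197 genes in vector cells, 137 and 196 in SPARCL1-labelled cells and 5 and 11 shared. The lines on Matrigel had 465 and 491 (r between the line ratios 0.743), 480 genes differed between ratios, and the ratio of the undetected SPARCL1 signals was 1.61. The median of the unfolded protein list over both surface ratios, -0.05, reversed to 0.015, so its small shared Matrigel difference depends on the signals used. The additive models and the authors' lists were not run with these signals, and the SPARCL1 level has no unfiltered alternative.
Without the other factor, the additive model called 0 genes for Matrigel instead of 15 (19 at an unadjusted limma p under the threshold) and 2635 instead of 2623 for the lines. The correlation between the ratios of the lines thus stayed positive in every setting run (r of at least 0.318), while the counts for Matrigel moved with the treatment of dim genes. Folds of switched-off genes rest on undetected signals and are nominal.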

Other observations

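The families and genes of this part were looked at after their values were seen, and no test was run on a family or group of them. Histone genes, whose replication-dependent members are made in S phase, went opposite ways on Matrigel. In vector cells 27 of 32 measured histone genes were lower on Matrigel than on plastic (median -0.45, percentile 0). In SPARCL1-labelled cells 24 of 30 were higher (median 0.13, percentile 99.85). Between the lines the median was -0.38 on plastic and 0.27 on Matrigel. The 2 medians largest in size both involve the vector plastic array, so the pattern rests largely on 1 array. The 4 medians share arrays, so their signs are not separate evidence. They kept their sign under quantile normalization and with the comparison tables' signals (-0.50 in vector cells and 0.11 in SPARCL1-labelled cells for Matrigel against plastic). H2AC8, present on all 4 arrays with a single alignment, was -0.99 on Matrigel in vector cells and 0.12 in SPARCL1-labelled cells. Several members are read by probe sets that align to more than 1 place or share a position with another member, so the counts overstate the number of separate readings. Keratin genes had a median between the lines of -0.12 on plastic (9 genes) and -0.98 on Matrigel (7 genes, all below 0), and -0.82 and -1.05 with the comparison tables' signals. KRT81 (5.06), KRT35 (0.68), KRT78 (0.51) and KRT25 (-0.03) counted on plastic alone, and KRT6B (-0.22) and KRT82 (-0.59) on Matrigel alone. The medians thus cover different members and do not compare the surfaces. Of the members measured on both, KRT10 was near 0 (-0.12 and -0.01) and KRT18 was -0.88 and -0.98. KRT7, KRT8 and KRT80 were also lower on both. MAGE genes, the last of the families looked at, had at most 2 measured members in any contrast.

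The 62 genes switched off in the SPARCL1-labelled line included the homeobox gene HOXA13, which marks the hindgut, and LGR4, a receptor for R-spondins. They also included EGF, a further ligand of the receptor that AREG binds, the protease-activated receptor F2RL1, the transcription factor TFAP2C and the myosin light chain MYL9. No enrichment was computed for them. EGF was dim, with signals of 37.1 and 59.8 on the vector plastic and vector Matrigel arrays. MYL9 only just passed the rule, at least 4.17-fold lower on plastic and at least 4.43-fold on Matrigel. For TFAP2C on Matrigel the authors' log2 ratio of vector over SPARCL1 was 2.7, but their change call was no change.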
